A study of Mus musculus with 8 samples.

How the data were processed

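Total RNA of mouse embryonic stem cells was hybridised to 8 arrays of Agilent design 028005, on 1 slide scanned on 1 date. Per the labels' protocols, 100 ng of total RNA was labelled with the Low Input Quick Amp kit. The labels name Cy5 as the dye while the scanner files hold a single channel under Agilent's name for green, and since each array has 1 channel this changes no direction. Per the file headers, Agilent Feature Extraction 11.0.1.1 made the processed signal, an intensity that is background-subtracted and spatially detrended and not scaled between arrays. The deposited scanner files also give the median signal and median local background of each spot, as intensity, and marks of 0 or 1 for spots that are well above background, saturated or outliers. The deposited value table of the series holds the same processed intensity on a linear scale, not centred, rounded to 3 digits (largest difference 0.5%). Its medians were 29.9, 23.5, 21.6 and 22.4 for replicate 1 of untreated, 4OHT 8h, 4OHT 10h and 4OHT 8h then PD0325901 2h, and 27.9, 26.5, 23.7 and 23.9 for replicate 2.

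Each array has 62976 spots, of which 3671 are control spots and were left out. Gene symbols were taken by matching the files' unversioned RefSeq accession to a RefSeq table of assembly GRCm38.p6, since the files give no symbol. Of 55681 non-control probes 27656 (49.7%) matched 1 symbol, 0 matched several and 28025 matched none and kept the file's name. The array design uses build mm9, so no coordinates are given. No spot was saturated (0 on each array), and 169 to 249 spots per array were marked as outliers and left out on that array. The lowest signal well above background was 6.68 to 9.58 on the arrays of replicate 1 and 14.82 to 19.96 on those of replicate 2.

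Log2 of the processed signal minus the array's 75th percentile over non-control spots was analysed in R 4.3.3 with limma 3.58.1 and the data.table package (1.17.8), after reading with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3. Spots of a probe were averaged, and a probe was kept if well above background on both arrays of at least 1 group (30336 probes). A gene was represented by its kept probe with the highest mean. For 5352 genes several probes were kept. Among called genes with another kept probe, that probe was called the opposite way for 9 of 1180 at 4OHT 8h, 16 of 1505 at 4OHT 10h and 1 of 280 in the inhibitor comparison, none of them named here. Another probe was called the same way for 718, 953 and 120 of these genes, in that order. For many genes the call was thus not repeated by another probe. A model with a mean per group was fitted to all 8 arrays (residual degrees of freedom 4, prior 1.71, median residual SD 0.129), with two-sided moderated tests, Benjamini-Hochberg adjustment over the genes tested, a threshold of 0.05 and no fold minimum. A gene called is one past that threshold.

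The groups, the comparisons, the tests, 22 gene lists and the rule for naming genes were fixed before the data were examined. The lists, written from general knowledge of embryonic stem cells and ERK signalling, were ERK feedback and ETV genes, immediate early genes, ligand and protease genes of RAF/ERK signalling, naive pluripotency, general pluripotency, formative and primed epiblast, primitive endoderm, primitive streak and mesendoderm, neural progenitor, trophoblast, two-cell-like state, LIF and STAT3 targets, BMP and SMAD targets, WNT targets, sterol biosynthesis, ribosome biogenesis and MYC targets, G2 and M phase of the cell cycle, p53 targets, integrated stress and unfolded protein response, SRF and YAP cytoskeletal targets, glycolysis and hypoxia, and fibroblast markers. They were tested two-sided with limma's camera at a preset correlation of 0.01, adjusted over the lists within a comparison, for lists of 5 or more tested genes. The naming rule took, in the comparisons of each 4OHT group with untreated cells and of PD0325901 with 4OHT 10h, the 6 largest rises and 6 largest falls among called genes with a proper symbol, above background on both arrays of the higher group and with no overlap between the groups' arrays. It also took up to 4 called members of each list with the smallest adjusted p (or the 2 with the smallest p where no member was called), and always Dusp6, Spry2, Spry4, Etv4, Etv5, Egr1, Fos, Myc, Nanog, Klf2, Klf4, Esrrb, Tbx3, Pou5f1, Sox2, Gata6, Pdgfra and Fgf5. In the other comparisons it took 3 rises and 3 falls and the same fixed genes, and for the reversal 6 genes each way with the largest smaller change. The rule orders genes by fitted change, which gives no order to genes not above background in a group, so no rank is given. Not every gene it took is named, and some results are not reported here.

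Labels give each group replicates 1 and 2, which are also the rows of the slide, while the slide column goes with the group and cannot be told apart from it. Deviations from the group means correlated between same-numbered arrays at 0.29 to 0.36 in all 6 pairs of groups, and a principal component with 11.9% of the variance separated the numbers. The numbers were therefore taken to pair the samples, a pairing that comes from the data and not from the labels. The fit without the block stayed the main one, and the block is given where it changes a call.

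Alternatives were quantile normalization, the array median in place of the 75th percentile, normexp (offset 50) with quantile normalization, the series value table, no filter on dim probes (36983 genes), probes well above background on all 8 arrays (19647 genes), outlier spots kept, the mean of a gene's probes, every probe on its own, an intensity trend and robust prior, the replicate block, only the groups compared, a minimum absolute log2 change of 1, each array left out in turn, and for lists an estimated correlation and fry. Normexp was planned on the mean signal, but the files hold no such column, so the median signal was used with the median background. With 1 array left in a group, that array was assumed to vary like the other groups' arrays. The fit was tested on simulated data for 4OHT 8h against untreated (22693 genes, 5 runs, 200 changed genes per run). It recovered 6.8%, 58.8%, 87.6% and 92.0% of genes changed by 0.5, 1, 2 and 3 on the log2 scale, with 6.6% of calls false. In the data 4932 genes were called in this comparison, so the adjustment is less strict there. The recovery rates therefore do not carry over to the data. A naive pluripotency list shifted by -1 was called in 20 of 20 simulated runs, and 12 of 420 tests of other lists were called. Genes with a left-out value (28) were not used in list tests.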

Results

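Gene expression was measured in mouse embryonic stem cells on 8 single-colour Agilent arrays, 2 for each of 4 groups. All cells grew with LIF, a cytokine that keeps these cells undifferentiated, and 250 nM PD173074, an inhibitor of FGF receptors. The groups were untreated cells, cells given 250 nM 4OHT (4-hydroxytamoxifen) for 8 h, cells given 4OHT for 10 h, and cells given 4OHT for 8 h and then 1 µM PD0325901, an inhibitor of the kinase MEK, for 2 h. 4OHT switches on proteins fused to a modified oestrogen receptor, but the labels name no such protein in these cells and do not say whether 4OHT stayed in the medium during the 2 h of inhibition. The series title names Erk, the kinase that MEK activates, so the comparisons asked which transcripts followed 4OHT and which of those depended on continued MEK activity. Values are log2 signals relative to each array's 75th percentile, and changes are log2 differences between group means ± the standard error of the limma fit. Each group had 2 arrays, and that number limits the precision. The p-values measure the spread between these samples, which may be technical, since the design text speaks of biological replicates but nothing states how the cultures were kept apart.

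Between 30218 and 37789 of the 59305 non-control spots on an array were well above background, with 36889 or more on each array of replicate 1 and 31433 or fewer on each array of replicate 2. The 75th percentile of the processed signal ranged from 309.0 to 392.6. Of the 22693 genes and unnamed features tested, 14498 carried a gene symbol. Replicates of the untreated cells correlated at r = 0.9931 across genes and those of the inhibited cells at r = 0.9934. The 4OHT 8h and 4OHT 10h arrays of replicate 1 lay closer to each other (r = 0.9971) than to the other replicate of their own group (0.992 and 0.9927), while those of replicate 2 did not (0.9903).

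The comparison of 4OHT 8h with untreated cells asked which transcripts had followed 4OHT. Of the 22693 tested, 4932 were called, 2329 higher and 2603 lower, and 4931 of them moved the same way in both replicate numbers. Centred on the array median, 3038 were higher and 1512 lower. At least 2-fold changes were seen for 1684 of them, 849 higher and 835 lower. The count fell to 2852 without untreated replicate 1, 2583 without 4OHT 8h replicate 1, 2833 without untreated replicate 2 and 2269 without 4OHT 8h replicate 2.

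Feedback inhibitors of ERK signalling rose. Dusp6, which encodes an ERK phosphatase, stood at 3.45 ± 0.02 (SD, n = 2) in untreated cells and at 6.29 ± 0.04 (SD, n = 2) after 8 h of 4OHT, a rise of 2.84 ± 0.09 or 7.16-fold (adjusted p = 0.00019). Spry4 rose by 3.01 ± 0.16 (adjusted p = 0.000388), Spry2 by 1.70 ± 0.10 (0.000497), Spred1 by 1.92 ± 0.07 (0.000206) and Etv4 by 1.79 ± 0.08 (0.000302). Dusp5 rose by 3.93 ± 0.13 (0.000206) from an untreated level well above background on 1 of 2 arrays. Etv5 was not called (-0.03 ± 0.08, adjusted p = 0.843). Of the 19 ERK feedback and ETV genes tested, 15 rose and 2 fell, with 16 and 2 adjusted over the list alone. The 2 that fell, named after their values were seen, were Dusp7 (-0.59) and Ccnd1 (-0.73). The list's median change was 1.54 (camera, adjusted p = 6.48e-10), and this was the only list of this comparison still called with an estimated correlation (0.0454).

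The immediate early genes, which ERK signalling induces without new protein synthesis, rose as well. Egr1 rose by 3.83 ± 0.29 or 14.2-fold (adjusted p = 0.00103), Fos by 2.52 ± 0.33 (0.00558), Myc by 2.37 ± 0.15 (0.000675), Fosl1 by 3.94 ± 0.15 (0.000219) and Arc by 2.83 ± 0.11 (0.000231). Fosl2 rose by 4.34 ± 0.30 (0.00083), from 1 of 2 untreated arrays well above background. Of 24 such genes tested, 18 rose and 0 fell in the limma fit, with 18 and 2 adjusted over the list alone and 19 and 2 with the replicate block. Their median was 1.57 (adjusted p = 1.57e-10 by camera, and adjusted p = 0.0771 with an estimated correlation). Among ligand and protease genes of RAF/ERK signalling, Plaur rose by 3.46 ± 0.12, Hbegf by 2.00 ± 0.15 and Epha2 by 1.15 ± 0.11. Mmp9 was not well above background in untreated cells and rose at least 7.04-fold. Such bounds set the brighter group's mean against the lowest signal of any spot well above background on each of the dimmer group's arrays, or the probe's own where that was higher. In that list 7 of 16 rose and 0 fell in the limma fit, with 9 and 0 adjusted over the list alone and 9 and 1 with the block, and with a median of 1.01 (adjusted p = 0.000347, and adjusted p = 0.109 with an estimated correlation).

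**Figure D1:**
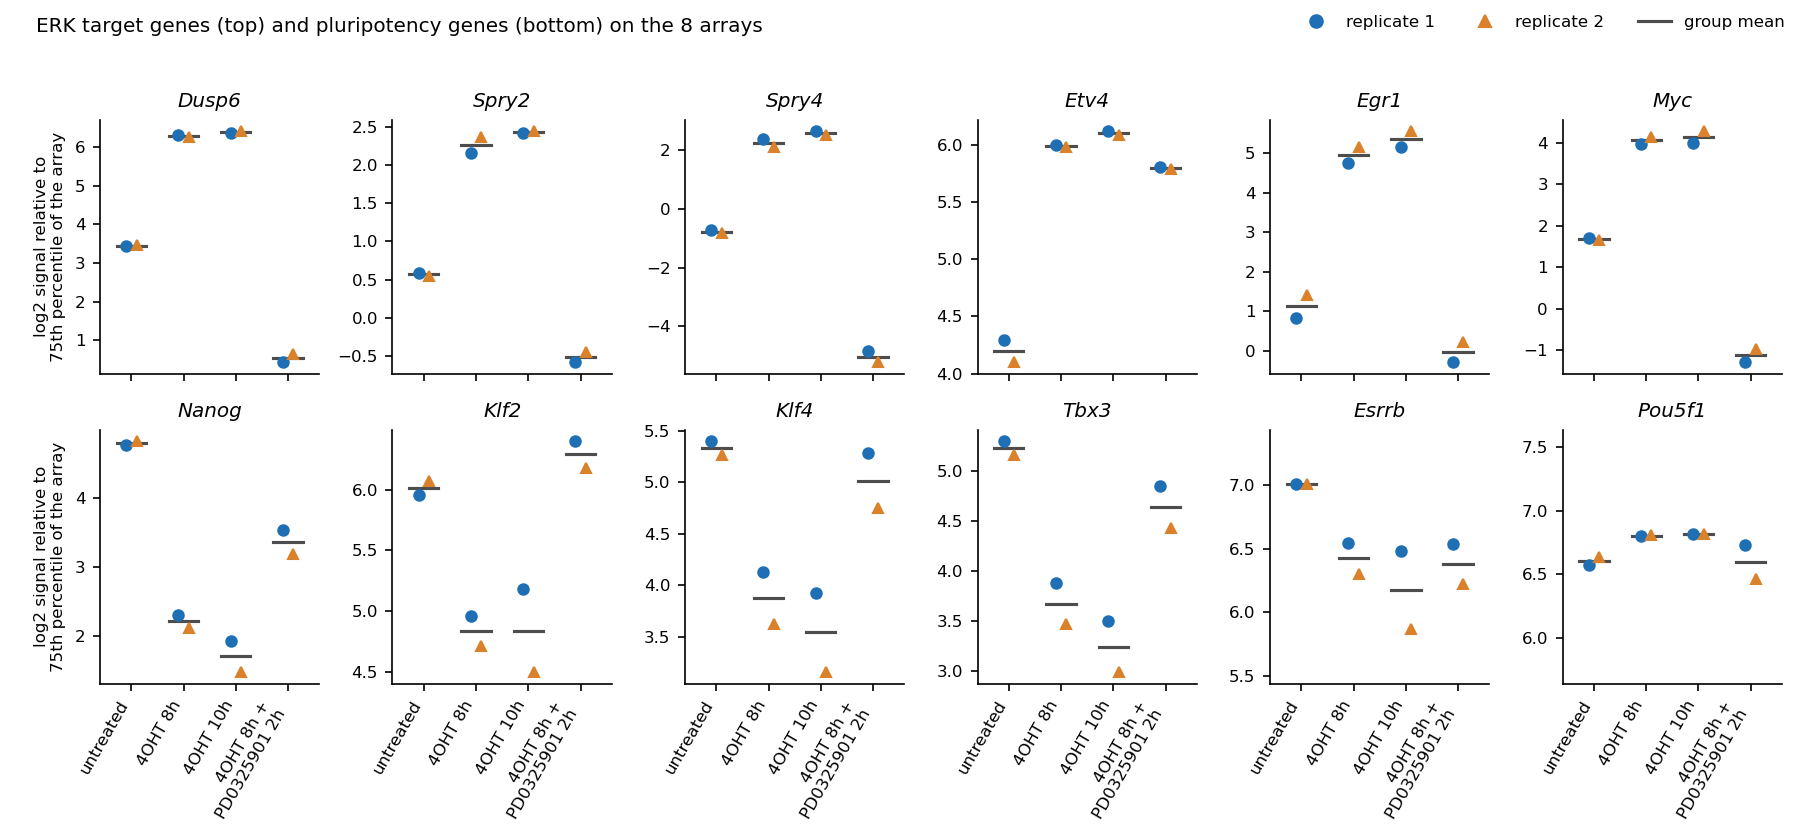
Log2 level relative to each array's 75th percentile (vertical axis) of 12 genes on each of the 8 arrays, by group (horizontal axis), 1 point per replicate. Dusp6 stood at 3.43 and 3.46 in untreated cells, 6.32 and 6.26 at 4OHT 8h, and 0.43 and 0.65 after PD0325901, while Nanog went from 4.78 and 4.83 to 2.31 and 2.12 and back to 3.54 and 3.19.

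Nanog, a transcription factor of naive pluripotency, fell by 2.59 ± 0.19 on the log2 scale at 8 h, or 6.04-fold (adjusted p = 0.000886). Fgf4 fell by 1.64 ± 0.10 (0.000646) and Tbx3 by 1.55 ± 0.24 (0.00949), the latter with adjusted p = 0.0541 without untreated replicate 1 and 0.0512 without 4OHT 8h replicate 2. Klf4 fell by 1.46 ± 0.32 (0.0281) and Klf2 by 1.18 ± 0.23 (0.0198). Both calls were lost when any of the 4 arrays compared was left out, at 0.117, 0.0561, 0.095 and 0.129 for Klf4 and at 0.0755, 0.0571, 0.0906 and 0.0995 for Klf2 (without untreated replicate 1, 4OHT 8h replicate 1, untreated replicate 2 and 4OHT 8h replicate 2, in that order), and with no filter on dim probes (0.0844 and 0.0655). Esrrb was not called (-0.58 ± 0.23, adjusted p = 0.128), but was with the replicate number as a block (0.0417). Manba rose by 1.79 ± 0.09 and Gbx2 by 2.68 ± 0.16 against this direction. Of 20 naive pluripotency genes, 9 fell and 5 rose, with 11 and 5 adjusted over the list alone, and the median was -0.87. That list was not called (adjusted p = 0.0927) but was with the replicate block (0.0315), centred on the array median (0.0121), under normexp (0.0281) and without 4OHT 10h replicate 1 or without 4OHT 10h replicate 2 (0.0425 in each).

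Pou5f1 was not called at 8 h (0.20 ± 0.10, adjusted p = 0.222). Sox2 was not called (0.28 ± 0.08, adjusted p = 0.07), but was centred on the array median (0.0376) and with an intensity trend and robust prior (0.0288). Other general pluripotency genes rose, Jarid2 by 1.01 ± 0.07 (adjusted p = 0.000837), Dppa4 by 0.95 ± 0.08 (0.00127) and Utf1 by 0.93 ± 0.08 (0.00141). In that list 7 of 18 rose and 0 fell in the limma fit, with 10 and 0 adjusted over the list alone, and the median was 0.28 (adjusted p = 0.000347, and adjusted p = 0.263 with an estimated correlation). Of the formative and primed epiblast genes, which mark the state after naive pluripotency, Pou3f1 rose by 3.30 ± 0.19 (0.000485), Sox4 by 1.44 ± 0.14 (0.00218) and Foxd3 by 0.82 ± 0.11 (0.00533). In that list 8 of 19 rose and 1 fell, with 9 and 2 adjusted over the list alone and 12 and 3 with the block, and the median was 0.60 (adjusted p = 0.00377, and adjusted p = 0.662 with an estimated correlation). The gene that fell, named after its value was seen, was Sall2 (-1.55). Fgf5, another of them, was not called (1.04 ± 0.49, adjusted p = 0.192) but was with the replicate block (0.0152).

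Large rises at 8 h included that of Cdx2, a transcription factor of trophoblast and hindgut, by 6.37 ± 0.43 or 82.5-fold (adjusted p = 0.0008), and that of the retinoic acid hydroxylase Cyp26a1, by 5.61 ± 0.10 (5.41e-05) from 1 of 2 untreated arrays well above background. Grm6 rose at least 99.8-fold, Krt23 at least 32.8-fold, Slc35f1 at least 31.2-fold and Nol4 at least 22.0-fold, none of them well above background in untreated cells. Large falls were those of the Nodal inhibitor Lefty1 (-5.77 ± 0.36, or 54.6-fold, adjusted p = 0.000654), Spic (-4.75 ± 0.28, 26.8-fold) and Hhip (at least 10.9-fold). Rasgef1a (-4.31 ± 0.35), Rasgrp1 (-4.14 ± 0.34) and the Nodal co-receptor gene Cfc1 (-4.01 ± 0.42) also fell, each well above background on 1 of the 2 arrays at 4OHT 8h.

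The trophoblast, primitive streak, WNT and BMP lists held genes that went both ways. Among trophoblast genes Hand1 rose at least 13.3-fold, Bmp4 by 2.51 ± 0.18 and Krt18 by 1.70 ± 0.18, and in that list 5 of 16 rose and 3 fell, with 7 and 4 adjusted over the list alone (median 0.21, adjusted p = 0.139). The 3 that fell, named after their values were seen, were Esx1 (-1.02), Tfap2c (-1.76) and Ascl2 (-1.35). Among primitive streak and mesendoderm genes, T (brachyury) rose by 3.59 ± 0.25 (from 1 of 2 untreated arrays well above background) and Eomes by 2.00 ± 0.12, while Lefty2 fell by 2.25 ± 0.10. In that list 5 of 16 rose and 6 fell, with 5 and 7 adjusted over the list alone (median -0.20, adjusted p = 0.794). Of the WNT targets Sp5 rose by 3.49 ± 0.10 and Tcf7 by 1.12 ± 0.12, and Tcf7l1 fell by 1.34 ± 0.11, with 4 of 15 up and 4 down, or 4 and 5 adjusted over the list alone (median -0.08, adjusted p = 0.858). Of the BMP and SMAD targets Id1 rose by 2.53 ± 0.17 and Msx1 by 2.21 ± 0.26, and Id4 fell by 1.53 ± 0.22. There 3 of 12 rose and 3 fell, with 3 and 4 adjusted over the list alone and 4 and 5 with the block, and the median (-0.22) and mean (0.11) differed in sign (adjusted p = 0.872).

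The median of the primitive endoderm list differed more between the replicates than between groups, where it was -0.19 to 0.12. This did not hold for each gene, as Lamb1 (0.12) and Lrp2 (-0.15) differed little between the replicates. Gata6 was 1.95 higher on the log2 scale in replicate 1 than in replicate 2 on average, and Pdgfra, well above background on 1 of 2 arrays at 4OHT 8h and at 4OHT 10h, was 2.21 higher. The median difference over the 24 genes of this list was 1.45, and by group it was 1.38 in untreated cells, 1.51 at 4OHT 8h, 1.61 at 4OHT 10h and 1.15 after PD0325901. In all 4 groups 21 of the 24 were higher in replicate 1. Gata6 was therefore not called at 8 h (0.54 ± 1.15, adjusted p = 0.78) but was with the replicate block (0.00433), and Pdgfra was not called (-0.23 ± 1.32, adjusted p = 0.924). Lamb1 (0.58 ± 0.11, adjusted p = 0.0161) and Lrp2 (0.83 ± 0.16, 0.0164) rose. Neither call held without untreated replicate 1 (0.0654 and 0.0816), without 4OHT 8h replicate 1 (0.0827 and 0.0676), without untreated replicate 2 (0.0741 and 0.0597) or with no filter on dim probes (0.0661 and 0.0603), nor did that of Lrp2 without 4OHT 8h replicate 2 (0.0835). With the replicate block 4 of the 24 rose and 5 fell, against 2 and 0 in the limma fit without it, and 2 and 0 adjusted over the list alone. The list was not called (median -0.19, camera upward, adjusted p = 0.794).

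**Figure D2:**
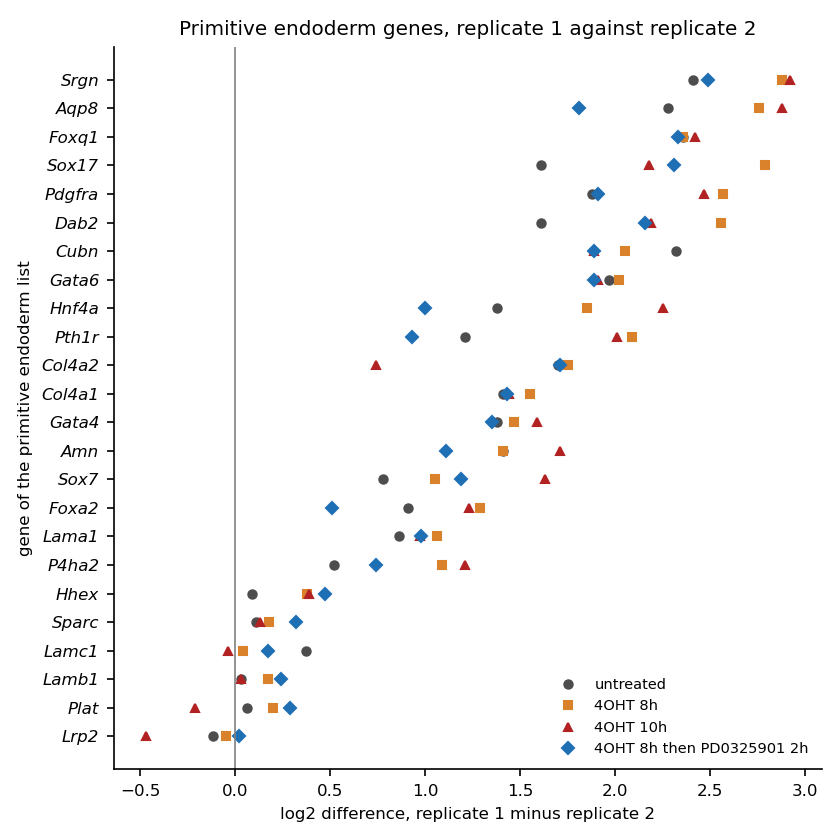
Replicate 1 minus replicate 2 (log2, horizontal axis) for each tested primitive endoderm gene (vertical axis), 1 point per group. The median over the 24 genes was 1.45, against 0.18 for Sparc and 1.95 for Gata6.

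The sterol biosynthesis genes Msmo1 (1.02 ± 0.10, adjusted p = 0.00206) and Idi1 (0.64 ± 0.08, 0.00478) rose, and in that list 13 of 25 rose and 2 fell, with 14 and 2 adjusted over the list alone and 15 and 4 with the block (median 0.40, adjusted p = 7.66e-05, and adjusted p = 0.533 with an estimated correlation). The 2 that fell, named after their values were seen, were Tm7sf2 (-0.65) and Mvk (-0.51). Of the ribosome biogenesis and MYC targets Ddx21 rose by 0.73 ± 0.08 and Gnl3 by 0.53 ± 0.07, and 12 of 24 rose and 0 fell in the limma fit, with 17 and 0 adjusted over the list alone (median 0.30, adjusted p = 6.45e-08, and adjusted p = 0.109 with an estimated correlation). Of the LIF and STAT3 targets Noct rose by 2.13 ± 0.10 and Socs2 by 1.94 ± 0.10, and Spp1 fell by 1.08 ± 0.07. There 6 of 18 rose and 3 fell, with 8 and 3 adjusted over the list alone, and the list was called upward (median 0.34, adjusted p = 0.0479, and adjusted p = 0.838 with an estimated correlation). That call was lost under quantile normalization (0.0896), median centring (0.167) and normexp (0.0639), and without 4OHT 8h replicate 1 (0.156), untreated replicate 2 (0.184), 4OHT 8h then PD0325901 2h replicate 1 (0.0607) or 4OHT 8h then PD0325901 2h replicate 2 (0.0608).

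The comparison of 4OHT 10h with untreated cells asked whether the response held over 2 more hours. It called 6332 genes, 2978 higher and 3354 lower (4861 and 1852 centred on the array median), of which 6330 moved the same way in both replicate numbers and 2116 by at least 2-fold. The count fell to 3874 without untreated replicate 1, 3931 without 4OHT 10h replicate 1, 4056 without untreated replicate 2 and 3170 without 4OHT 10h replicate 2. Dusp6 rose by 2.95 ± 0.09 (adjusted p = 0.000108), Spry4 by 3.36 ± 0.16 (0.000226), Egr1 by 4.24 ± 0.29 (0.000628), Fos by 3.09 ± 0.33 (0.00238) and Myc by 2.46 ± 0.15 (0.000445). Etv5 was again not called (-0.05 ± 0.08, adjusted p = 0.691). Nanog fell by 3.10 ± 0.19 (0.000427) and Tbx3 by 1.98 ± 0.24 (0.00352). Klf4 fell by 1.79 ± 0.32 (0.0121, but 0.0637 without untreated replicate 1 and 0.0519 without untreated replicate 2). Klf2 fell by 1.17 ± 0.23 (0.0167, but 0.0653 and 0.0767 without the same arrays, 0.0545 with no filter on dim probes and 0.06 with only the groups compared). Pou5f1 was not called (0.22 ± 0.10, adjusted p = 0.17, and 0.0412 centred on the array median), nor was Sox2 (0.24 ± 0.08, adjusted p = 0.0875, and 0.0265 and 0.041 centred on the median and with an intensity trend). The block called Gata6 (0.68, adjusted p = 0.0019 against 0.688) and Fgf5 (0.93, adjusted p = 0.0176 against 0.205).

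Esrrb fell by 0.84 ± 0.23 at 10 h (adjusted p = 0.0414). That call was lost without untreated replicate 1 (0.138), 4OHT 8h replicate 1 (0.0617), 4OHT 8h then PD0325901 2h replicate 1 (0.0565), untreated replicate 2 (0.129), 4OHT 8h replicate 2 (0.0617), 4OHT 10h replicate 2 (0.129) or 4OHT 8h then PD0325901 2h replicate 2 (0.0565), centred on the median (0.106), with no filter on dim probes (0.113) and with only the groups compared (0.0892).

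Large rises at 10 h were those of Krt23 (at least 64.1-fold), Grm6 (at least 118-fold), Cdx2 (92.6-fold), Nol4 (at least 19.7-fold), the retinaldehyde dehydrogenase gene Aldh1a3 (6.09 ± 0.33, from 1 of 2 untreated arrays well above background) and Slc35f1 (at least 44.0-fold). Large falls were those of Lefty1 (61.3-fold), Rasgef1a (at least 21.3-fold), Hhip (at least 11.5-fold), Spic (26.6-fold), Gsc (at least 7.26-fold) and Lmo1 (-4.26 ± 0.53, above background on 1 of 2 arrays at 10 h). Of the ERK feedback and ETV genes 15 of 19 rose and 1 (Dusp7, -0.68) fell, with 16 and 1 adjusted over the list alone (median 1.72, adjusted p = 3.11e-09, and adjusted p = 0.0522 with an estimated correlation). Of the immediate early genes 18 of 24 rose and 0 fell in the limma fit, with 18 and 1 adjusted over the list alone and 20 and 1 with the block (median 1.89, adjusted p = 1.12e-10, and adjusted p = 0.0752 with an estimated correlation). The ligand and protease list was called (10 of 16 up and 0 down, the same adjusted over the list alone, and 11 and 1 with the block, adjusted p = 9.86e-05, and adjusted p = 0.108 with an estimated correlation), as were general pluripotency (8 up and 1 down of 18, or 9 and 1 adjusted over the list alone, 0.000387, and adjusted p = 0.268 with an estimated correlation) and formative epiblast (10 up and 2 down of 19, or 10 and 4 adjusted over the list alone and 13 and 5 with the block, 0.00566, adjusted p = 0.672 with an estimated correlation, and 0.0576 centred on the median). Sterol biosynthesis was called with 17 up and 2 down of 25, the same adjusted over the list alone, and 18 and 4 with the block (median 0.64, adjusted p = 5.91e-06, and adjusted p = 0.413 with an estimated correlation), and ribosome biogenesis with 13 up of 24, or 16 adjusted over the list alone (adjusted p = 4.01e-07, and adjusted p = 0.108 with an estimated correlation). Of the naive pluripotency genes 10 of 20 fell and 5 rose, with 12 and 5 adjusted over the list alone. That list was not called (median -0.81, adjusted p = 0.108) but was with the replicate block (0.0424), under median centring (0.00879) and normexp (0.034) and without 4OHT 10h replicate 1 (0.0295).

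Both 4OHT groups were set against the same untreated arrays. In both 2163 genes rose and 2318 fell, against 305.6 and 384.7 for independent sets of those sizes and 2914 and 1304 when centred on the array median, and 0 went opposite ways in the limma fits. In 50 simulations of unchanged groups against shared arrays, at most 1 gene overlapped. Few genes can be called where nothing changes, so this count does not measure what the shared arrays add to the overlap. The changes correlated at r = 0.92 (Spearman's rho 0.87) across 22692 genes, which are not independent replicates, against 0.5 in simulation, and their covariance was 0.498 against 0.031. Part of the excess over independent sets may come from the shared untreated arrays, which were not split since that leaves 1 array for each comparison. The 4481 genes of the overlap became 2656 without untreated replicate 1, 2337 without 4OHT 8h replicate 1, 2652 without untreated replicate 2, 2183 without 4OHT 8h replicate 2 and 2802 without 4OHT 10h replicate 2.

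The comparison of PD0325901 for the last 2 h with 4OHT 10h matched the time since 4OHT was added and asked which transcripts depended on MEK. It called 1389 genes, 737 higher and 652 lower (490 and 682 centred on the array median), all of which moved the same way in both replicate numbers, and 558 changed at least 2-fold. Of the 1389 genes, 206 were called neither at 4OHT 8h nor at 4OHT 10h against untreated. No group was given PD0325901 without 4OHT. An effect of the inhibitor on the 4OHT response thus cannot be told apart from one on levels without 4OHT. The replicate block called 2821. The count fell to 411 without 4OHT 8h then PD0325901 2h replicate 1, 462 without 4OHT 8h then PD0325901 2h replicate 2, 574 without 4OHT 10h replicate 1, 371 without 4OHT 10h replicate 2, and 868 without either 4OHT 8h replicate 1 or 4OHT 8h replicate 2. Spry4 fell by 7.62 ± 0.16 or 197-fold (adjusted p = 0.000118), to a level above background on 1 of 2 arrays (-5.09 under normexp). Dusp6 fell by 5.85 ± 0.09 or 57.8-fold (5.28e-05), Egr1 by 5.39 ± 0.29 or 42.0-fold (0.00141), Myc by 5.26 ± 0.15 or 38.4-fold (0.00028) and Fos by 4.35 ± 0.33 (0.00316). The homeobox gene Gsx1 fell by 6.71 ± 0.49 or 104-fold (0.00263) and Ptger2 at least 14.2-fold. Spry2 fell by 2.94 ± 0.10 (0.000359) and Dusp5 by 2.53 ± 0.13 (0.0014). Etv4 was not called (-0.31 ± 0.08, adjusted p = 0.107) except with an intensity trend and robust prior (0.0357), and Etv5 was not called (-0.08 ± 0.08, adjusted p = 0.616).

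Of the ERK feedback and ETV genes 12 of 19 fell with PD0325901 and 0 rose in the limma fit, with 15 and 1 adjusted over the list alone and 14 and 1 with the block (median -1.26, adjusted p = 3.56e-13). Of the immediate early genes 17 of 24 fell and 1 rose, with 19 and 1 adjusted over the list alone (median -1.65, adjusted p = 4.94e-15). Both lists remained called with an estimated correlation (0.0259 and 0.0401). The immediate early gene that rose was Atf3 (2.11 ± 0.27, adjusted p = 0.0136), with 0.0845 without 4OHT 8h then PD0325901 2h replicate 1, 0.0648 without 4OHT 8h then PD0325901 2h replicate 2, 0.0779 without 4OHT 10h replicate 2 and 0.0606 with no filter on dim probes. Hbegf fell by 3.56 ± 0.15, Epha2 by 2.67 ± 0.11 and Plaur by 1.55 ± 0.12, and in the ligand and protease list 4 of 16 fell and 1 (Plat, 1.47 ± 0.14) rose, with 5 and 1 adjusted over the list alone and 9 and 1 with the block (adjusted p = 0.000712, and adjusted p = 0.159 with an estimated correlation). Large rises were those of Neurog3 (4.73 ± 0.22 or 26.5-fold, adjusted p = 0.00118), Rasgef1a (at least 11.3-fold), Pramel30 (at least 6.97-fold), Spic (4.10 ± 0.28) and Grin2c (3.82 ± 0.22).

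Nanog rose by 1.66 ± 0.19 with PD0325901 (adjusted p = 0.00996, but 0.057 without 4OHT 8h then PD0325901 2h replicate 1 and 0.075 with only the groups compared), and Fgf4 by 1.32 ± 0.10 (0.00339). Klf2 rose by 1.45 ± 0.23 (0.0265) and Tbx3 by 1.39 ± 0.24 (0.0325). The Klf2 call was lost without 4OHT 8h then PD0325901 2h replicate 1 (0.127) or 4OHT 8h then PD0325901 2h replicate 2 (0.0971), without 4OHT 10h replicate 2 (0.0606), without either untreated replicate 1 or untreated replicate 2 (0.0602) and without either 4OHT 8h replicate 1 or 4OHT 8h replicate 2 (0.0522). The Tbx3 call was lost without 4OHT 8h then PD0325901 2h replicate 1 (0.136) or 4OHT 8h then PD0325901 2h replicate 2 (0.0784), 4OHT 10h replicate 1 (0.0552), 4OHT 10h replicate 2 (0.137), or either untreated array (0.0691), and under median centring (0.0524). Both were also lost with no filter on dim probes (0.0989 and 0.117) and with only the groups compared (0.122 and 0.116). Klf4 was not called (1.47 ± 0.32, adjusted p = 0.0614) but was with the replicate block (0.00966), under normexp (0.0125), with probes well above background on all 8 arrays (0.0425) and with an intensity trend and robust prior (0.0208). Esrrb was not called (0.21 ± 0.23, adjusted p = 0.657). Gbx2 fell by 4.37 ± 0.16 (0.000544). Of the naive pluripotency genes 5 of 20 rose and 3 fell, with 6 and 6 adjusted over the list alone and 7 and 5 with the block (median 0.18, adjusted p = 0.233).

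Sox2 fell by 0.83 ± 0.08 with PD0325901 (adjusted p = 0.00697, and 0.0511 with only the groups compared), while Pou5f1 was not called (-0.22 ± 0.10, adjusted p = 0.286). Of the general pluripotency genes 6 of 18 fell and 0 rose in the limma fit, with 8 and 0 adjusted over the list alone (median -0.29, adjusted p = 1.78e-05, and adjusted p = 0.191 with an estimated correlation). Among formative and primed epiblast genes Otx2 fell by 2.34 ± 0.18 (0.00303), Foxd3 by 2.01 ± 0.11 (0.0014) and Sox4 by 1.59 ± 0.14 (0.00468). In that list 4 of 19 fell and 0 rose in the limma fit, with 5 and 0 adjusted over the list alone and 7 and 0 with the block (adjusted p = 0.00812, adjusted p = 0.566 with an estimated correlation, 0.113 without 4OHT 8h then PD0325901 2h replicate 1 and 0.0526 without 4OHT 10h replicate 2). Bmp4 fell by 3.56 ± 0.18, Id3 by 2.69 ± 0.13, Id1 by 2.36 ± 0.17 and Smad7 by 2.19 ± 0.15. The BMP and SMAD list had 5 of 12 down and 2 up, or 6 and 4 adjusted over the list alone (adjusted p = 0.233), and the trophoblast list 2 of 16 up and 2 down, or 3 and 4 adjusted over the list alone and 4 and 4 with the block (adjusted p = 0.892). Lefty1 rose by 3.59 ± 0.36, and of the primitive streak genes 3 of 16 rose and 4 fell, or 4 and 5 adjusted over the list alone (median -0.06, adjusted p = 0.892). Gata6 was not called (-1.04 ± 1.15, adjusted p = 0.663) but was with the replicate block (0.00304). Of the primitive endoderm genes 1 of 24 (Plat) rose and 0 fell in the limma fit, and the same adjusted over the list alone, with 4 and 1 under the block (median 0.07, adjusted p = 0.246, but 0.0121 without 4OHT 10h replicate 1 and 0.0143 without 4OHT 8h then PD0325901 2h replicate 2).

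The LIF targets Noct (-3.47 ± 0.10), Pim1 (-2.15 ± 0.10) and Socs2 (-1.30 ± 0.10) fell with PD0325901, and in the LIF and STAT3 list 7 of 18 fell and 3 rose, with 7 and 5 adjusted over the list alone and 10 and 6 with the block. The list was not called (adjusted p = 0.056) but was under quantile normalization (0.0483) and normexp (0.0148), without 4OHT 8h then PD0325901 2h replicate 1 (0.025) and without 4OHT 10h replicate 2 (0.0109). Of the WNT targets Sp5 fell by 1.63 ± 0.10 and Ccn4 rose by 1.62 ± 0.14, with 3 of 15 up and 2 down, or 4 and 2 adjusted over the list alone and 3 and 4 with the block (median -0.01, mean 0.26, adjusted p = 0.4). Sterol biosynthesis was called downward (median -0.13, adjusted p = 0.0272) but not with an estimated correlation (0.594), the replicate block (0.0519), quantile normalization (0.0906), or without 4OHT 10h replicate 1 (0.0899) or 4OHT 8h then PD0325901 2h replicate 2 (0.168). Of its 25 genes 1 (Msmo1) fell and 0 rose in the limma fit, the same adjusted over the list alone, and 3 fell with the block. Ribosome biogenesis was called downward (median -0.15, adjusted p = 0.00336) with 0 of 24 genes called by limma, also 0 adjusted over the list alone, and not with an estimated correlation (0.251), quantile normalization (0.42) or normexp (0.853). Ddx21 in it changed by -0.27 ± 0.08 (adjusted p = 0.125, and 0.047 with an intensity trend and robust prior).

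**Figure D3:**
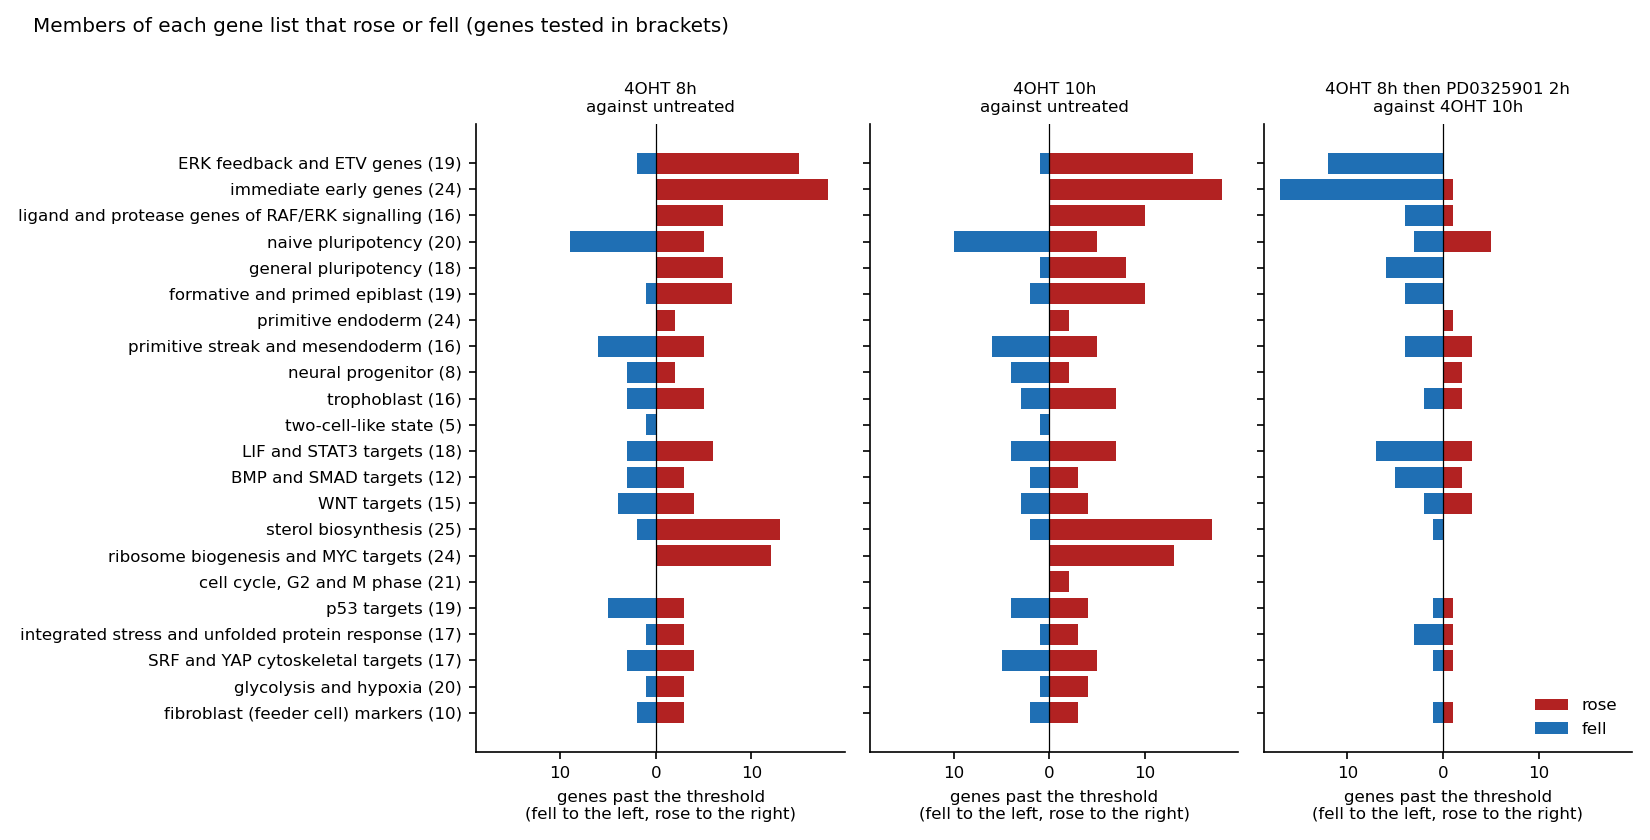
Genes of each of 22 lists that rose (bars to the right) or fell (bars to the left) in 3 comparisons, as counts of genes on the horizontal axis and lists on the vertical axis. Of the immediate early genes 18 rose at 4OHT 8h and 17 fell with PD0325901, while of the sterol biosynthesis genes 13 rose and 1 fell.

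The reversal of the 8 h response was read from comparisons that share no arrays but use 1 estimate of each gene's spread from all 8 arrays. A gene with a small spread is more easily called in both, so counts for independent sets are a rough reference. Without a group given PD0325901 alone, an opposite change need not be an undoing of the 4OHT response. Of the 2329 genes that rose at 8 h, 532 fell with PD0325901, 7.95 times the 66.9 that independent sets would share and 81.6% of the 652 that fell. Of the 2603 that fell at 8 h, 538 rose with PD0325901, 6.37 times the 84.5 of independent sets and 73.0% of the 737 that rose. Centred on the array median, these counts were 588 and 339. In the same direction went 16 genes that rose in both (75.6 for independent sets) and 5 that fell in both (74.8). Besides Egr1, genes moving far both ways were Gsx1 (4.49 at 8 h, -6.71 with PD0325901), Ptger2 (4.36, then down at least 14.2-fold), Phlda1 (4.33 and -4.09), Cyp26a1 (5.61 and -3.65) and the endothelin gene Edn2 (3.32 and -3.33), with Ptger2, Cyp26a1 and Edn2 above background on 1 of 2 untreated arrays. In the other direction were Rasgef1a (-4.31, then up at least 11.3-fold), Spic (-4.75 and 4.10), Neurog3 (-3.98 and 4.73), Hoxb13 (down at least 8.35-fold, then up at least 8.33-fold), Lefty1 (-5.77 and 3.59) and Rasgrp1 (-4.14 and 3.59, the latter with adjusted p = 0.0552 with only the groups compared). The genes that rose at 8 h had a median change of -0.31 with PD0325901 and 91.6% of them the opposite sign (camera, p = 3.16e-41, and 0.000339 with an estimated correlation). For those that fell at 8 h the median was 0.28 and 85.3% had the opposite sign (1.91e-45, and 0.000679 with an estimated correlation). Across 22692 genes, which are not independent replicates, the changes correlated at r = -0.56 (Spearman's rho -0.53), against 0 in simulations of unchanged groups. The 1070 reversed genes became 2137 with the replicate block, and 654, 601, 422 and 331 without replicate 1 and 665, 602, 307 and 380 without replicate 2 of untreated, 4OHT 8h, 4OHT 10h and 4OHT 8h then PD0325901 2h, in that order.

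**Figure D4:**
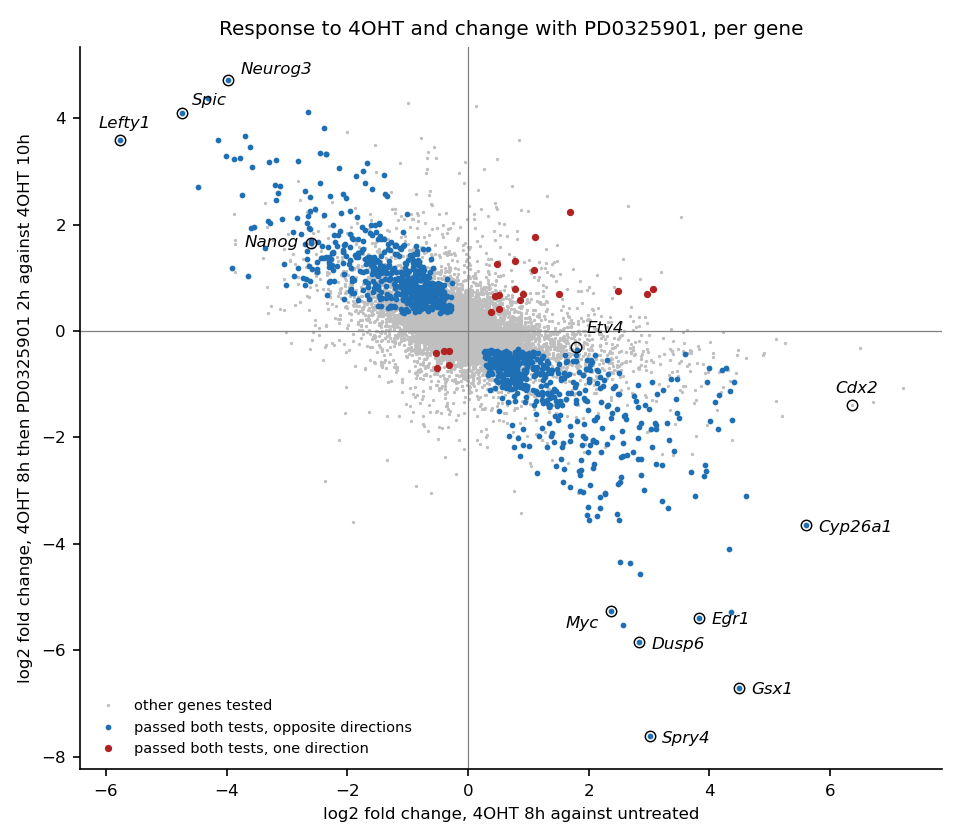
Log2 change at 4OHT 8h against untreated (horizontal axis) and log2 change of 4OHT 8h then PD0325901 2h against 4OHT 10h (vertical axis), 1 point per gene, with genes called in opposite directions coloured. The 532 genes that rose at 8 h and fell with PD0325901 lie at the lower right and the 538 that fell and then rose at the upper left.

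Set against 4OHT 8h, the start of the inhibition, PD0325901 called 1479 genes, 773 higher and 706 lower, a comparison in which time differed as well. The replicate block called 3184. The count fell to 532 without 4OHT 8h replicate 1, 391 without 4OHT 8h replicate 2, 432 without 4OHT 8h then PD0325901 2h replicate 1 and 435 without 4OHT 8h then PD0325901 2h replicate 2. Spry4, above background on 1 of 2 arrays after PD0325901, fell by 7.27 ± 0.16 (adjusted p = 0.000154, and -4.75 under normexp), as did Gsx1 (-5.92 ± 0.49, 0.00424), Dusp6 (-5.74 ± 0.09, 5.89e-05), Myc (-5.17 ± 0.15, 0.00031), Egr1 (-4.99 ± 0.29, 0.0015) and Ptger2 (at least 19.7-fold). Neurog3 (4.78 ± 0.22), Rasgrp1 (4.30 ± 0.34) and Grin2c (4.27 ± 0.22) rose. Sox2 fell by 0.87 ± 0.08 (0.00657), and neither Etv4 (-0.19 ± 0.08, adjusted p = 0.261) nor Etv5 (-0.10 ± 0.08, 0.523) was called. The block called Klf4 (1.14, adjusted p = 0.0159 against 0.111), Tbx3 (0.96, 0.00954 against 0.0826) and Gata6 (-0.89, 0.00398 against 0.712). The ERK feedback list fell (11 of 19 down and 0 up in the limma fit, or 14 and 2 adjusted over the list alone and 14 and 2 with the block, median -1.21, adjusted p = 1.94e-11, and adjusted p = 0.0343 with an estimated correlation), as did the immediate early genes (15 of 24 down and 1 up, or 16 and 1 adjusted over the list alone, median -1.28, adjusted p = 5.66e-12, and adjusted p = 0.0611 with an estimated correlation).

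The comparison of PD0325901 with untreated cells asked what was left of the response after 2 h of inhibition. It called 3594 genes, 1600 higher and 1994 lower (1871 and 915 centred on the array median), and the replicate block called 6283. The count fell to 1561 without untreated replicate 1, 1468 without untreated replicate 2, 1655 without 4OHT 8h then PD0325901 2h replicate 1 and 1192 without 4OHT 8h then PD0325901 2h replicate 2. Spry4, above background on 1 of the 2 inhibited arrays, was lower than in untreated cells by -4.26 ± 0.16 (adjusted p = 0.000319, and -2.03 under normexp), Dusp6 by -2.90 ± 0.09 (0.000261), Myc by -2.81 ± 0.15 (0.000813), Spry2 by -1.08 ± 0.10 (0.00316) and Myo1f by -3.31 ± 0.30 (0.00316). Egr1 (-1.16 ± 0.29, adjusted p = 0.0513) and Fos (-1.26 ± 0.33, 0.0574) were not called. Both were with the block (0.0017 and 0.0133), with an intensity trend (0.0206 and 0.0269) and with probes well above background on all 8 arrays (0.0364 and 0.0412). Egr1 was also called under normexp (0.0245), and Fos without 4OHT 10h replicate 1 or 4OHT 10h replicate 2 (0.0438) and with only the groups compared (0.0267). Etv4 remained higher by 1.61 ± 0.08 (0.000689). Krt23 (at least 30.5-fold), Grm6 (at least 46.8-fold) and Nol4 (at least 15.8-fold) stayed far above untreated. Nanog remained lower (-1.44 ± 0.19, adjusted p = 0.00873, and 0.0505 without untreated replicate 2), while Klf2 (0.28 ± 0.23, 0.463), Klf4 (-0.32 ± 0.32, 0.538) and Pou5f1 (-0.01 ± 0.10, 0.966) were not called. The block called Esrrb (-0.63, adjusted p = 0.038), Tbx3 (-0.59, 0.0188), Gata6 (-0.35, 0.0184) and Fgf5 (0.95, 0.0236), none called otherwise. Of the ERK feedback and ETV genes 6 of 19 were higher than in untreated cells and 5 lower, or 6 and 6 adjusted over the list alone (median -0.06, camera upward, adjusted p = 0.716). Sterol biosynthesis (11 of 25 up and 1 down, or 15 and 2 adjusted over the list alone and 14 and 3 with the block, median 0.36, adjusted p = 6.03e-06) and ribosome biogenesis (7 of 24 up, or 10 adjusted over the list alone, median 0.19, adjusted p = 3.24e-05) stayed up, each with adjusted p = 0.365 with an estimated correlation. The trophoblast list was called upward too (7 of 16 up and 2 down, the same adjusted over the list alone, median 0.61, adjusted p = 0.0193), but not with an estimated correlation (0.365), centred on the array median (0.0784) or without 4OHT 8h then PD0325901 2h replicate 2 (0.058).

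Between 4OHT 8h and 4OHT 10h, 0 genes were called by limma, with 1501 at an unadjusted p under 0.05 and 0 with the replicate block and under every other setting that kept all arrays. Leaving out 4OHT 8h replicate 1, 4OHT 10h replicate 1 or 4OHT 8h replicate 2 gave 2, 4 and 1. Dusp6 changed by 0.11 ± 0.09 (adjusted p = 0.886), Fos by 0.56 ± 0.33 (0.827) and Nanog by -0.51 ± 0.19 (0.741). As lists the immediate early genes were still called upward (median 0.30, adjusted p = 1.01e-05, and adjusted p = 0.249 with an estimated correlation), as was sterol biosynthesis (median 0.16, adjusted p = 7.23e-06, and adjusted p = 0.556 with an estimated correlation). Of both lists 0 genes were called by limma, also 0 adjusted over the list alone.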

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

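No test in this part was chosen after the result was seen. Counts are given in the order 4OHT 8h, 4OHT 10h and PD0325901 against untreated, then PD0325901 against 4OHT 10h and against 4OHT 8h, then the reversal and the overlap of both 4OHT responses. With no filter on dim probes they became 2303, 3306, 1069, 333, 358, 279 and 2132, with more genes tested. With only the groups compared they were 2767, 3980, 1413, 328, 328, 250 and 2429, with fewer arrays in each fit. A minimum absolute log2 change of 1 left 1684, 2116, 1107, 558, 577, 392 and 1552. The replicate block raised the counts of 4OHT 8h and 4OHT 10h to 7247 and 8861 and the overlap to 6537. It raised those with PD0325901 to 6283, 2821 and 3184 and the reversal to 2137. The block takes the difference between replicate numbers, correlated at 0.29 to 0.36 between groups, out of the residual spread. How much of the rise in counts this accounts for was not tested. Beyond the genes, lists and member counts for which it is given, the block changed no gene's or list's call in the report. It moved no other member count there by more than 1.5 times. Leaving out each array in turn gave 2269 to 4269, 3170 to 5866, 1192 to 2649, 371 to 959, 391 to 1063, 307 to 665 and 2183 to 3896, with fewer arrays in each fit. For 4OHT 10h against 4OHT 8h it gave 0 to 4 genes. The remaining settings kept these counts within 1.5 times. Centring on the median moved the median of all genes to 0.141 at 4OHT 10h against untreated and to -0.117 with PD0325901 against 4OHT 10h (from -0.047 and -0.04), and the share of called genes that were higher went from 47.2% to 66.8%, 47.0% to 72.4%, 44.5% to 67.2%, 53.1% to 41.8% and 52.3% to 51.3%. Which direction held more genes thus turned in all of these but PD0325901 against 4OHT 8h. Of 22 lists, 8, 7, 3, 9 and 9 were called, and 5 between the 4OHT groups. These became 1, 0, 0, 2, 1 and 0 with an estimated correlation, which widens the null of each list, and 13, 15 and 10 against untreated and 1 between the 4OHT groups under fry, 6 for PD0325901 against untreated with the block and 8 between the 4OHT groups under normexp, the cause was not tested. Array omission gave 3 to 6 lists for PD0325901 against untreated and 4 to 9 between the 4OHT groups. A list was called in the direction opposite to the main fit in 3 tests, none of them called there, the BMP and SMAD list at 4OHT 10h (0.0363) and the ERK feedback list after PD0325901 against untreated (0.00462), both under fry, and the primitive endoderm list between the 4OHT groups without 4OHT 8h replicate 1 (0.0395, with 0.0187 to 0.97 over the arrays left out), the cause was not tested. All 302 calls of genes taken by the naming rule kept their direction, and 235 of them stayed called under every setting. The filter on all 8 arrays gave no value for 64 of the 371 tests of these genes. Signal over background limited the dimmest groups, so that bounds replaced folds for genes such as Krt23 and Grm6.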

Other observations

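Tests reported here were chosen after the result was seen, with 3 exceptions. These are the planned list tests, the tests of genes taken by the naming rule, and the test of a second list of endoderm genes. That last test was written before its result was seen. The rules for reading the test of the second list and the one of an effect of 4OHT outside MEK were made stricter after their results were seen. Among lists outside the report, neural progenitor genes were called upward by camera with PD0325901 against 4OHT 10h (adjusted p = 0.0186, and adjusted p = 0.205 with an estimated correlation), with Tubb3 up by 1.18 ± 0.10, and this was lost under normexp (0.0702) and without either untreated replicate 1 or untreated replicate 2 (0.0636). At 4OHT 8h, where Tubb3 fell and Nes rose by 1.43 ± 0.12, that list was not called (adjusted p = 0.794). Glycolysis and hypoxia was called downward with PD0325901 (median -0.19, adjusted p = 0.0219), but not with an estimated correlation (0.251), quantile normalization (0.104), normexp (0.172) or without 4OHT 10h replicate 1 (0.0908). At 4OHT 8h the p53 targets (adjusted p = 0.398), the integrated stress and unfolded protein response (0.872), the SRF and YAP cytoskeletal targets (0.872), the fibroblast markers (0.794, median -0.05 and mean 0.64), the two-cell-like state (0.665) and G2 and M phase (0.738) were not called. In G2 and M phase 0 genes were called by limma (1 and 1 up and down with the replicate block, and 0 adjusted over the list alone). In the other lists Pmaip1 (2.19 ± 0.24), Xbp1 (1.32 ± 0.08), Zyx (1.23 ± 0.11) and Twist1 (3.13 ± 0.23) rose, while Ei24 (-1.04 ± 0.09), Cth (-0.67 ± 0.07), Amotl2 (-0.89 ± 0.09) and Fbln2 (-1.06 ± 0.16) fell.

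Primitive endoderm genes were 1.45 higher (median of 24) in replicate 1 than in replicate 2, while 10000 random lists matched on mean level gave at most 0.15, which excludes a difference between the slide rows that depends on signal alone. A larger share of primitive endoderm cells in replicate 1 may be the reason and stays open. A second list of 22 endoderm genes differed by 0.1, above 99.7% of matched lists. The naive pluripotency (0.22), LIF and STAT3 (0.18) and sterol biosynthesis (0.11) lists differed by more, so this second test is not particular to endoderm. The naive difference was 0 in untreated cells, 0.21 at 4OHT 8h, 0.38 at 4OHT 10h and 0.31 after PD0325901. It was thus seen only in cells given 4OHT, unlike that of the first endoderm list. The formative and primed epiblast (-0.36), trophoblast (-0.21), p53 (-0.18) and SRF and YAP (-0.12) lists differed the other way. Of the first list 12 of 24 genes were higher by over 1 in all 4 groups, against 0 in each of these other lists. Lama1 (mean level 5.49) differed by 0.97. Sparc (0.18), Lamb1 (0.12) and Lamc1 (0.14) differed by little, at mean levels of 8.06, 5.03 and 5.23. High levels in these cells could hide a small share, which was not tested, and level alone does not set Lama1 apart from Lamb1 and Lamc1. Beyond that share of cells no biological explanation was tested, since the labels name no difference between the replicates.

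Spry4, Dusp6, Myc and Spry2 lay below their untreated level after PD0325901. Over 5 scalings the smallest of their falls was -0.79 ± 0.08 (Spry2, under normexp), against a largest shift of the median gene of 0.07. The choice among these scalings thus does not account for the falls. Each scaling fixes a percentile or the quantiles of the array, which keeps that shift small, so scaling in general is not excluded. ERK output that PD173074 leaves in untreated cells may explain the falls of these 4 genes and stays open. The median of the 19 ERK feedback genes was -0.06 with a standard error of 0.32, and its members went both ways. Dusp4 (2.38) and Spred3 (1.65), chosen after their values were seen, stayed above untreated (Spred3 being above background on 1 of 2 untreated arrays), and Il17rd (-1.11) below.

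The 13 sterol biosynthesis genes that rose at 4OHT 8h changed by a median of -0.23 ± 0.08 with PD0325901 against 4OHT 10h. Lists matched on the rise at 8 h and on level gave -0.43 to -0.16, with the sterol genes at the 77.4th percentile, so the small fall may be chance. Against 4OHT 8h the median was -0.07 ± 0.06, at the 99th percentile of matched lists. An effect of 4OHT that does not run through MEK stays open. Nor do the arrays measure how long transcripts made before the inhibition last. The comparison with 4OHT 8h also differs by 2 h in time, and the one matched in time showed no excess. The labels do not say whether 4OHT was present during these 2 h.

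Of 22665 genes, 63 differed between the replicates by more than 1 with the same sign in all 4 groups, 34 higher in replicate 1 and 29 in replicate 2. Genes chosen after their values were seen were Ddx3y, Eif2s3y and Peg13, given as replicate 1 minus replicate 2 on the log2 scale. Ddx3y differed by 2.22 (4.67-fold), Eif2s3y by 0.09 and Peg13 by -5.39. The mean level of Peg13 in replicate 1 (-5.48) was near the lowest signal well above background there.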
